A study of Zea mays with 13 samples.

How the data were processed

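Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was run on immature wrapped leaves of the maize inbred B73. Antibodies against H3K4me3, H3K9ac and H3K27me3 were used on well-watered (NS) and drought-stressed (WS) plants, at the end of the stress (T0) and after recovery (T7). This gave 12 immunoprecipitated libraries, 1 for each mark and group, and 1 library of whole chromatin without immunoprecipitation, 13 samples in all. Per the labels, the deposited values are raw read counts, not normalized, with a table for each mark holding 4 libraries and a table for whole chromatin holding its counts in a 1 kb window at the transcription start site and over the whole gene. CASAVA 1.8 and Bowtie2 are named in the submitters' processing notes, with B73 RefGen_v4 as the genome. The counting program, the window used to count each mark and any removal of duplicate reads are not given in the sources used here. Whether the tissue of several plants was pooled is likewise not given.

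The count windows of the marks were checked from the values. H3K27me3 counts followed the whole-gene counts of whole chromatin, with Spearman correlations across genes of 0.889 to 0.910, and so were set against these. H3K4me3 and H3K9ac counts gave 0.424 to 0.460 with the whole-gene counts and less, 0.124 to 0.304, with the 1 kb window. Short genes went the other way. At microRNA genes the median count of well-watered plants at T0 was 2 for H3K27me3 against 27 at other genes, but 16 against 94 for H3K4me3 and 18 against 28 for H3K9ac, where whole chromatin had 68 against 66 in the 1 kb window and 9 against 143 over whole genes. Both active marks were set against the 1 kb window as an assumption. It sets the levels of enrichment, the marked genes, the quintiles, the background genes and the ratios with the trend on enrichment removed, so that whole-gene counts were tried as well, though not for scaling on background genes. The whole-chromatin library is labelled as control plants after 10 days and served as background for all groups, so that differences in whole chromatin between groups were not measured. Every table held 43943 features, 43789 gene models of the RefGen_v4 series and 154 microRNA genes. None of the 43789 gene model IDs (a count of 0) was found in the reference table used here, which belongs to the later Zm-B73-REFERENCE-NAM-5.0 assembly. These genes are therefore given by ID without name, function or position. The microRNA genes are named in the tables, and 153 of the 154 names occur among the reference synonyms.

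With 1 library per group there is no replicate, no SD and no test of the conditions between a pair of groups. Each such comparison used a rule of size. Counts were scaled by TMM over the 4 libraries of the mark, and a gene had to have at least 40 counts over these libraries. A gene met the rule when its scaled ratio was at least 1.5-fold and the exact 99.9% conditional binomial (Clopper-Pearson) interval of the ratio left out 1. The intervals printed beside single genes are 95% intervals of the same kind. They cover counting error only, take the scaling as known and leave out the variation between plants and between immunoprecipitations. Log2 ratios carry a prior of 0.5 counts in each library. The number of genes that the rule takes by counting error alone was simulated 20 times per comparison.

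A test with residual spread was possible only by fitting all 4 libraries of a mark together. edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) was run with additive terms for watering and time, which leaves 1 residual degree of freedom per gene before sharing across genes, with Benjamini-Hochberg adjustment at 0.05. In this model the difference between the drought effects of both times serves as the error. A further model tested that difference itself, with the mean drought effect as the error. DESeq2 1.42.0 was run as the alternative tool for each model. Adjusted p-values printed for genes are those of edgeR's quasi-likelihood test.

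Enrichment was the log2 ratio of scaled counts over whole chromatin, for genes with at least 20 whole-chromatin counts. A gene was called marked when its enrichment was at least 2-fold above the 25th percentile of the library in all 4 libraries of the mark. Contrast of a library is the fold between the 95th and the 25th percentile of enrichment. Lists of genes were compared with 10000 random lists of the same size matched on counts, as a description of these libraries.

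The groups, the rule of size, the additive model, the rule for naming genes, the gene lists and all alternatives but those named as added below were fixed before the data were examined. The definition of marked genes, the model of the difference, the comparison of T7 with T0 in stressed plants, the removal of a trend on enrichment, the whole-gene counts as its background and the use of the microRNA genes as a list were added after that. Genes were named by rule: for each mark and drought comparison the 8 higher and 8 lower genes whose 99.9% interval lay farthest from 1, then up to 5 genes that met the rule in the same direction at both times, up to 5 that met it alike for H3K4me3 and H3K9ac, and up to 5 that met it in opposite directions for H3K27me3 and an active mark. For the time comparison 5 genes a direction were taken. Of genes without a name, at most 2 a direction are printed for a mark and comparison. The gene lists of drought, abscisic acid, flowering and related functions relied on names or descriptions, so that no list could be matched and no list median was computed.

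The alternatives were scaling by total counts, DESeq2 size factors, scaling on the 10% of genes with the lowest enrichment (background genes), removal of a loess trend on abundance (span 0.3), no filter on low counts, a filter at 200 counts, the added loess trend on enrichment, and the same trend with enrichment of the active marks over whole-gene counts, added after the results were seen. Scaling on background genes moved the median log2 ratio of all H3K4me3 genes to -0.70 for drought at T0, to -0.83 for time in well-watered plants and to -0.13 for time in stressed plants. The H3K9ac medians moved to -0.45 for drought at T0 and to -0.47 for time in well-watered plants. All directions given for genes are relative to the TMM scaling.

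The procedure was tested on simulated data in which 50 genes were changed at each fold, with the means and library sizes of the real libraries. Counts for the rule held counting error only, and those for the fits had a common dispersion for all genes. Real ratios spread more. In the highest quintile of H3K4me3 enrichment their robust SD between the T0 libraries was 0.18, against 0.13 from counting. The values below are thus not error rates of the real comparisons. The rule recovered 70%, 36% and 30% of the 2-fold changes for H3K4me3, H3K9ac and H3K27me3 between the T0 libraries, and took 16, 18 and 21 unchanged genes among the 35748, 40817 and 33794 tested. The additive edgeR fit recovered 80%, 26% and 38% of 2-fold drought effects present at both times, and 32%, 4% and 6% of 1.5-fold effects. It took 9, 8 and 4 unchanged genes among the 35668, 40741 and 33844 tested. DESeq2 on the same simulated counts recovered 28%, 0% and 2% of the 2-fold effects and 0% of the 1.5-fold effects for each mark, 70%, 4% and 34% of the 3-fold and 74%, 20% and 58% of the 4-fold effects, and took 0 unchanged genes. The edgeR fit recovered 94%, 80% and 84% of the 4-fold effects. No genome sequence was used, so sequence context, gene length and GC content were not analysed here.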

Results

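Read counts of 3 histone marks were compared in young maize leaves after drought and after recovery. H3K4me3 and H3K9ac accompany active promoters, and H3K27me3 is laid down by Polycomb complexes at silenced genes. Plants of the inbred B73 were grown with normal watering and then kept for 10 days either well watered (75% of disposable water) or under mild drought (25%). Immature wrapped leaves, which were still enclosed by older leaves, were taken at the end of this period (T0) and after 7 days of recovery (T7). Each mark had 1 library for each of the 4 groups, well watered and stressed at T0 and at T7, so no difference between a pair of libraries has a replicate check.

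H3K4me3 libraries were the deepest. They held 6876219 counts over genes in well-watered and 2793985 in stressed plants at T0, and 4059090 and 5980217 at T7. In the same order of watering, H3K9ac libraries held 1856159 and 1580825 counts at T0 and 1241333 and 1152884 at T7. H3K27me3 libraries held 1861849 and 1804634 at T0 and 1612935 and 1969485 at T7. Whole chromatin gave 3055058 counts in the 1 kb windows at transcription start sites and 10976995 over whole genes. The filter on counts left 35654 features for H3K4me3, 41294 for H3K9ac and 33860 for H3K27me3. Counts of a mark ranked genes alike in all 4 libraries, with Spearman correlations across genes of 0.963 to 0.975 for H3K4me3, 0.864 to 0.894 for H3K9ac and 0.954 to 0.961 for H3K27me3.

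Which genes carried the marks was asked first, from enrichment over whole chromatin. H3K4me3 marked 26156 genes (60.0% of those with enough whole-chromatin counts), H3K9ac 13569 (31.1%) and H3K27me3 4245 (10.7%). H3K9ac lay almost wholly within the H3K4me3-marked genes: among 39427 genes measured for all marks, 13194 carried both where independent marks would give 8469, which is 99.8% of the H3K9ac-marked and 52.2% of the H3K4me3-marked genes. H3K4me3 stood alone at 9258 genes. H3K27me3 met H3K9ac at 430 genes against 1421 for independent marks, and H3K4me3 at 3231 genes against 2713. H3K27me3 stood without an active mark at 1005 genes, and 13140 genes (33.3%) carried none of the marks. Enrichment correlated across genes at 0.88 (Spearman) between H3K4me3 and H3K9ac, at -0.23 between H3K4me3 and H3K27me3 and at -0.28 between H3K9ac and H3K27me3. With whole-gene counts of whole chromatin as background for the active marks, 21107 genes were marked by H3K4me3 and 14991 by H3K9ac, 51.3% of the H3K9ac-marked genes above among them. H3K4me3 then covered 81.3% of the H3K9ac-marked genes, and H3K27me3 met H3K9ac at 2038 genes against 1609 for independent marks and H3K4me3 at 3005 against 2266, so that the low overlap of H3K27me3 with H3K9ac depends on the window.

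The effect of drought at the end of the stress was read from the stressed against the well-watered T0 libraries. H3K4me3 was higher in the stressed library at 443 genes and lower at 259, against 15.7 genes in either direction from counting error alone. Of these, 193 and 253 were H3K4me3-marked. H3K9ac was higher at 182 genes, 17 of them H3K9ac-marked, and lower at 343, 259 of them marked, against 24.8. Between the well-watered libraries of T7 and T0 the rule took more genes, 1086 for H3K4me3 and 593 for H3K9ac. Between waterings at T0 it took 702 and 525 in all. Genes higher or lower for H3K4me3 lay on the same side for H3K9ac more often than random lists. Of 193 H3K4me3-marked genes higher in the stressed library, 77.2% also lay above 0 for H3K9ac, with a median log2 ratio of 0.35, against 42.6% in random lists of marked genes. Of 252 lower genes, 77.0% lay below 0 for H3K9ac, with a median of -0.28, against 61.3% in random lists. The rule was met for both marks by 27 genes higher and 9 genes lower, where independent lists would give 1.67 and 2.51, and by 0 genes in opposite directions, where 4.31 (H3K4me3 higher) and 0.972 (H3K4me3 lower) would be given. It was met for both by 15 genes higher and 4 lower with the trend on enrichment removed, where 0.995 and 0.494 would be given, by 43 and 4 with total counts, 39 and 5 with the trend on abundance removed, 94 and 1 with a filter at 200 counts and 1 and 4326 with scaling on background genes. Of 259 H3K9ac-marked genes lower for H3K9ac, 76.1% lay below 0 for H3K4me3 against 69.5% in random lists, and with the trend removed 48.4% of 31 did against 50.1%, while of 85 then higher for H3K9ac 81.2% lay above 0 against 51.2%. The former depends on the window: with the trend on whole-gene enrichment removed, 72.3% of 202 genes lower for H3K9ac lay below 0 for H3K4me3 against 47.2% of all H3K9ac-marked genes.

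Among single genes at T0, Zm00001d041401 held 240 H3K4me3 counts in the stressed library and 137 in the deeper well-watered one, a log2 ratio of 2.07 (95% interval 1.76 to 2.38). Zm00001d011912 held 34 against 233 counts, a log2 ratio of -1.50 (-2.08 to -0.99). Zm00001d041401 was not H3K4me3-marked, and Zm00001d011912 was. Zm00001d005804 was higher for H3K4me3 (1.41, 1.04 to 1.78) and for H3K9ac (1.23, 0.74 to 1.75). Zm00001d020353 was lower for both (-0.85, -1.27 to -0.46, and -1.17, -1.81 to -0.59). Among the microRNA genes, zma-MIR408b was higher for H3K9ac (1.25, 0.54 to 2.03; 51 against 24 counts). The microRNA of this family acts on transcripts of copper proteins. H3K27me3-marked genes made up 4.13% of the H3K4me3-marked genes lower in the stressed library against 12.9% of the others, and 17.7% of those higher against 12.8%.

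Ratios at T0 also followed the strength of the mark. From the quintile of genes with the lowest enrichment to that with the highest, the median log2 ratio of stressed over well-watered plants went from 0.63 to -0.10 for H3K4me3 and from 0.41 to -0.22 for H3K9ac. The same trend appeared between the well-watered libraries of T7 and T0, from 0.60 to -0.12 and from 0.42 to -0.22, and contrast was highest in the well-watered T0 library, at 40.1-fold for H3K4me3 and 6.74-fold for H3K9ac against 22.4 to 23.0 and 4.50 to 4.82 in the others. With enrichment over whole-gene counts the differences between the highest and lowest quintiles were smaller, -0.38 for H3K4me3 and -0.15 for H3K9ac between waterings at T0 and -0.49 and -0.16 between the well-watered libraries, and contrast was again highest in the well-watered T0 library, at 33.7-fold against 20.2 to 24.3 and at 11.9-fold against 10.2 to 10.3. With the trend on enrichment removed, 281 genes were higher and 161 lower for H3K4me3, and 129 higher and 113 lower for H3K9ac. They were 421 and 295 for H3K4me3 and 148 and 432 for H3K9ac with the trend on whole-gene enrichment removed. Scaling by total counts gave 523 higher and 169 lower for H3K4me3 and 247 and 210 for H3K9ac, removal of the trend on abundance gave 179 and 135 for H3K9ac, and scaling on background genes gave 32 and 16777 for H3K4me3 and 12 and 5056 for H3K9ac.

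**Figure D1:**
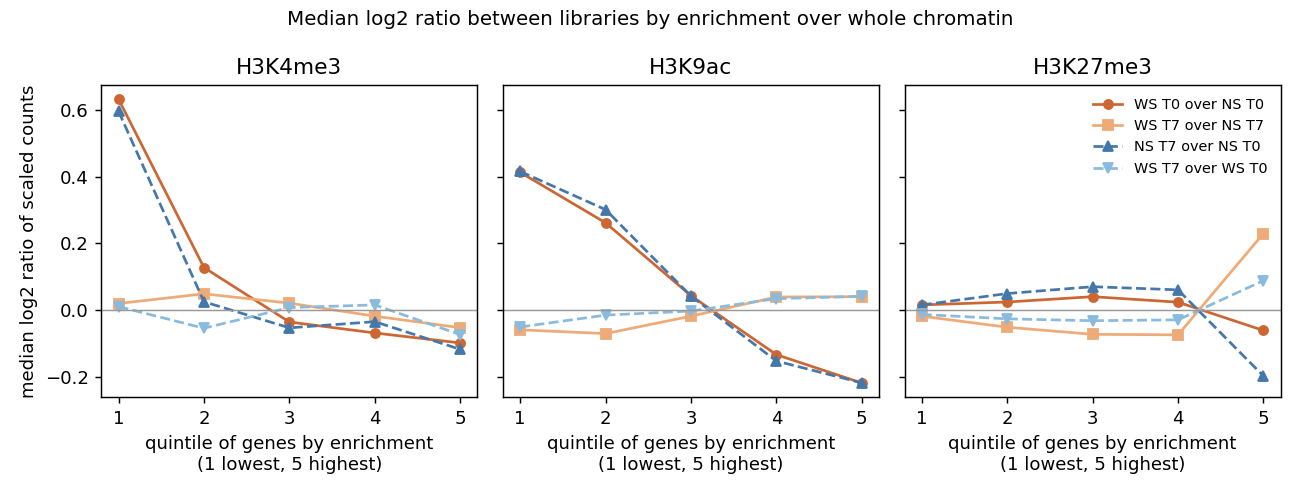
Median log2 ratio of scaled counts between a pair of libraries (y axis) for quintiles of the tested genes ordered by enrichment over whole chromatin (x axis, 1 lowest to 5 highest), 1 panel per mark and 1 line per pair of libraries. For H3K4me3 and H3K9ac both lines that have the well-watered T0 library as reference fall, from 0.63 to -0.10 and from 0.60 to -0.12 for H3K4me3, and for H3K27me3 the highest quintile stands apart where the well-watered T7 library is compared, at 0.23 and -0.20.

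H3K27me3 differed less at the end of the stress. It was higher at 37 genes and lower at 35 in the stressed library, against 20.8 from counting error. Of these, 1 of the higher and 16 of the lower genes were H3K27me3-marked. The rule took 72 genes in all here and 258 between the well-watered libraries of T7 and T0. Scaling on background genes gave 26 higher and 44 lower between waterings at T0. Zm00001d045735 was higher, with 64 against 24 counts (1.45, 0.77 to 2.21), and Zm00001d050338 was lower, with 3 against 23 (-2.70, -5.27 to -1.16). Neither was H3K27me3-marked. Zm00001d025055 met the rule for all 3 marks: H3K4me3 was higher in the stressed library (1.08, 0.79 to 1.36), as was H3K9ac (1.17, 0.585 to 1.801), and H3K27me3 was lower (-0.85, -1.27 to -0.45). It was not H3K27me3-marked. It was the only gene to meet the rule in opposite directions for H3K27me3 and an active mark at T0. Independent lists would give 0.374 and 0.274 such genes with H3K4me3 and 0.143 and 0.329 with H3K9ac, active mark higher before lower. A single gene is too few to read as an excess. Across genes the T0 drought ratios of H3K27me3 had Spearman correlations of -0.00027 with those of H3K4me3 and -0.017 with those of H3K9ac, and H3K4me3 and H3K9ac had 0.284, which was 0.0987 with the trend on enrichment removed and 0.2342 with the trend on whole-gene enrichment removed.

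**Figure D2:**
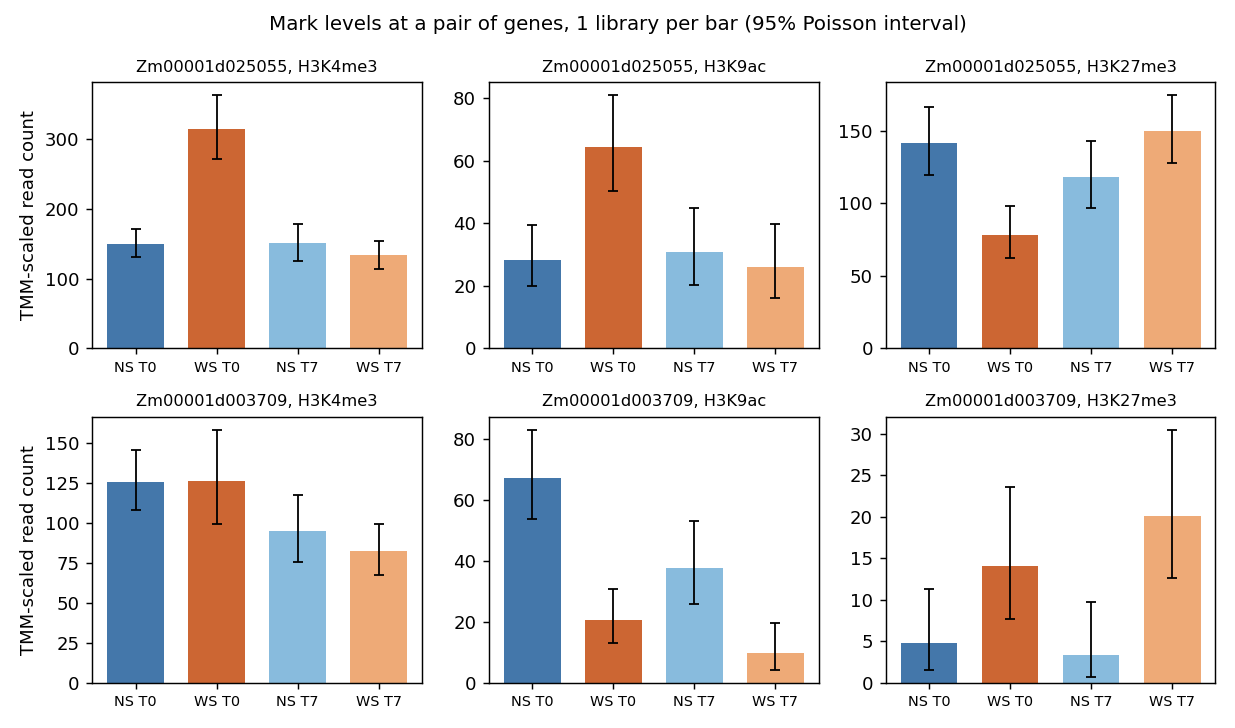
TMM-scaled read counts (y axis) of H3K4me3, H3K9ac and H3K27me3 in the 4 libraries of each mark (x axis: NS well watered, WS stressed, T0 end of stress, T7 after recovery) at Zm00001d025055 and Zm00001d003709, with bars of 1 library each and 95% Poisson intervals of the count. At Zm00001d025055 the stressed T0 library stands at 316 for H3K4me3, above 133 to 150 in the others, and at Zm00001d003709 H3K9ac is lower in stressed plants at both times, at 20.6 against 67.0 and at 9.92 against 37.7.

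After recovery the active marks of previously stressed and well-watered plants differed at few genes. H3K4me3 was higher at 35 genes and lower at 33, against 14.6 from counting error, and H3K9ac at 32 and 48, against 23.5. Genes that met the rule for H3K4me3 did not share a direction for H3K9ac beyond random lists, with 48.3% of 29 higher and 42.9% of 21 lower marked genes on the same side. H3K27me3 was higher in previously stressed plants at 144 genes and lower at 44, against 20.5 from counting error, and 113 of the higher genes and 0 of the lower ones were H3K27me3-marked. Over all 4120 tested marked genes the median log2 ratio was 0.29, and 79.3% lay above 0.

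Among genes with higher H3K27me3 at T7 were Zm00001d004630 (120 against 37 counts; 1.40, 0.87 to 1.98) and Zm00001d024665 (1.21, 0.75 to 1.71). Zm00001d043894 was lower (-1.79, -2.91 to -0.85). For H3K4me3, Zm00001d042182 was higher (1.81, 0.95 to 2.88) and Zm00001d022437 lower (-1.40, -1.83 to -0.99). For H3K9ac, Zm00001d026432 was higher (2.62, 1.23 to 4.74) and Zm00001d012883 lower, with 6 against 34 counts (-2.29, -3.93 to -1.12). Of the genes named here, Zm00001d043894, Zm00001d042182, Zm00001d026432 and Zm00001d012883 were not marked for the mark in question. H3K27me3 contrast was lowest in the well-watered T7 library, at 3.61-fold against 4.09 to 4.48, and with the trend on enrichment removed 28 genes were higher and 34 lower. Scaling by total counts gave 44 higher and 26 lower for H3K4me3 at T7, removal of the trend on abundance 26 and 40, and scaling on background genes 81 and 29 for H3K9ac.

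Whether differences at the end of the stress were still there after recovery was asked from comparisons that share no library. H3K4me3 was lower in stressed plants at both times at 2 genes, Zm00001d054081 (-1.52 at T0 and -3.41 at T7) and Zm00001d030656 (-0.88 and -0.68), where independent lists would give 0.240, and higher at both times at 0 genes, where 0.435 would be given. H3K9ac was lower at both times at 1 gene, Zm00001d003709 (-1.68 and -1.86), and H3K27me3 was higher at both times at 1 gene, Zm00001d030248 (0.63 and 0.73). Across genes the T0 and T7 drought ratios had Spearman correlations of 0.046 for H3K4me3, -0.048 for H3K9ac and -0.047 for H3K27me3.

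The additive fit over all 4 libraries asked for a drought effect shared by both times. Zm00001d054081 was the gene called for H3K4me3, with a log2 change of -2.54 ± 0.31 (SE; edgeR quasi-likelihood test, adjusted p = 8.94e-06) and counts of 106 and 81 in well-watered and 15 and 11 in stressed plants at T0 and T7. For H3K9ac it was Zm00001d003709, with -1.77 ± 0.31 (adjusted p = 0.000556) and counts of 85 and 33 against 23 and 8. Neither gene was marked, by the definition used here, for the mark it was called for. H3K27me3 at Zm00001d003709 went the other way, with 5 and 3 counts in well-watered and 14 and 22 in stressed plants, and met the rule at T7 (2.40, 0.85 to 4.97), though no longer with the trend on abundance or on enrichment removed (2.24 for the latter). No H3K27me3 gene was called (edgeR 0, unadjusted p under 0.05 at 1200 genes). DESeq2 called 0 genes for each mark, with an adjusted p of 1 for both genes and unadjusted p under 0.05 at 19 genes for H3K4me3, 13 for H3K9ac and 6 for H3K27me3. The edgeR count for H3K4me3 rose to 52 with the trend on abundance removed and to 13 with no filter on low counts.

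The change over the 7 days of recovery, in both waterings together, was tested in the same fit. H3K4me3 changed at 1392 genes in the additive fit, 310 higher and 1082 lower at T7 (edgeR quasi-likelihood test, adjusted p under 0.05). DESeq2 called 0 of the 35654 genes, with unadjusted p under 0.05 at 403 genes. Zm00001d041387 fell by 1.19 ± 0.11 on the log2 scale (SE, adjusted p = 8.8e-09) and Zm00001d016271 by 1.28 ± 0.15 (adjusted p = 1.14e-06), and Zm00001d005512 rose by 0.84 ± 0.10 (adjusted p = 1.14e-06) and Zm00001d019608 by 0.82 ± 0.11 (adjusted p = 6.07e-06). The fallers named here were H3K4me3-marked, and the risers named here were not. The fit takes the difference between waterings as its error, so that it favours genes that change alike in both. The genes lower at T7 had median ratios of -0.53 in well-watered and -0.53 in stressed plants. H3K9ac at these genes was also lower, with a median of -0.39 in well-watered and -0.20 in stressed plants, and 71.0% of them lay below 0 in stressed plants against 46.9% of the other H3K4me3-marked genes. H3K27me3 at the same genes had medians of 0.02 and 0.08. At the 310 genes higher at T7, H3K9ac lay above 0 at 71.0% in well-watered plants against 38.0% of the other H3K4me3-marked genes, and at 63.5% in stressed plants against 53.1%. Of the 180 of them that were H3K4me3-marked, 53.3% lay above 0 for H3K9ac in well-watered and 53.3% in stressed plants. The H3K9ac medians of these 180 lay at percentile 100 of random lists in well-watered and 38.9 in stressed plants.

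H3K27me3-marked genes were over-represented among the fallers and nearly missing among the risers. Of 1034 H3K4me3-marked genes that fell, 16.7% carried H3K27me3 against 12.6% of the other H3K4me3-marked genes (odds ratio 1.39, Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 0.000269 over 8 such comparisons). Of 176 that rose, 0.568% did against 12.9% (odds ratio 0.039, adjusted p = 3.12e-09). Genes are not independent replicates in these tests. Removal of the trend on enrichment left 1136 genes called, 491 higher and 645 lower, of which 855 were among the 1392, and the shares marked by H3K27me3 were then 22.3% of fallers and 1.43% of risers. H3K9ac-marked genes made up 69.0% of the H3K4me3-marked fallers against 51.5% of the others, and 53.0% against 52.2% with that trend removed. Among the risers they made up 55.7% against 52.2%, and 67.5% against 52.0% with it removed. Removal of the trend on whole-gene enrichment left 183 genes called, 180 of them among the 1392. Marked by that enrichment, 17.3% of 979 fallers carried H3K27me3 against 14.1% of the others, and 2.45% of 204 risers against 14.4%. For H3K9ac edgeR called 0 genes over time (unadjusted p under 0.05 at 1876; DESeq2 0, with 34) and for H3K27me3 0 (1327; DESeq2 0, with 6).

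Each watering on its own gave the time comparison in counts of genes that met the rule. In well-watered plants H3K4me3 was higher at T7 at 465 genes and lower at 621, and in stressed plants at 186 and 620, against 14.6 and 18.6 from counting error. The H3K4me3-marked among these were 145 and 605 in well-watered and 164 and 574 in stressed plants. The waterings share no library, and 113 genes were lower in both and 9 higher in both, where independent lists would give 10.8 and 2.43, while 19 went in opposite directions, where 11.3 would be given. After removal of the trend on enrichment, 58 were lower in both, 14 higher in both and 13 opposite, where 5.33, 1.74 and 6.63 would be given. H3K9ac was higher at 298 and lower at 295 genes in well-watered plants, 4 and 203 of them H3K9ac-marked, and at 54 and 73 in stressed plants. H3K27me3 was higher at 33 and lower at 225 in well-watered plants, 185 of the lower ones H3K27me3-marked, and at 41 and 26 in stressed plants. Zm00001d037769 and Zm00001d005609 were lower at T7 for both active marks in stressed plants, by H3K4me3 ratios of -1.27 and -1.40 and H3K9ac ratios of -1.68 and -1.53. In well-watered plants Zm00001d018165 was higher for both (1.33 and 1.05), though marked for neither.

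For the time comparison in well-watered plants, scaling by total counts gave 565 higher and 455 lower genes for H3K4me3, removal of the trend on abundance 471 and 417, and scaling on background genes 21 and 21148 for H3K4me3 and 14 and 4437 for H3K9ac. In stressed plants scaling on background genes gave 65 and 1122 for H3K4me3 and 99 and 44 for H3K9ac. Removal of the trend on enrichment gave 29 higher and 52 lower genes for H3K27me3 in well-watered plants.

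The 154 microRNA genes, of 28 families, were the features that the tables name. H3K4me3 marked 36 of them (23.4%), H3K9ac 15 and H3K27me3 1. Only 1 of them passed the filter on counts for H3K27me3, against 116 for H3K4me3 and 137 for H3K9ac. Their median whole-gene count of whole chromatin was 9, below the 20 needed for enrichment. H3K27me3 was thus hardly measured at microRNA genes, and its absence there cannot be read. H3K4me3 changed from T0 to T7 at 4 of 116 tested microRNA genes, no larger a share than the 1392 of 35654 (3.90%) over all tested genes. It rose at zma-MIR396a (0.86 ± 0.16, SE; edgeR adjusted p = 0.00117) and zma-MIR172c (0.84 ± 0.25, adjusted p = 0.0468), the latter not H3K4me3-marked. It fell at zma-MIR159e (-0.63 ± 0.16, adjusted p = 0.0149) and zma-MIR156k (-0.56 ± 0.17, adjusted p = 0.0459). The microRNA miR156 holds plants in the juvenile phase and miR172 promotes the adult phase and flowering, while miR396 acts on growth-regulating factors and miR159 on GAMYB transcription factors. Adjusted over the list alone, 2 of these remained, and DESeq2 called 0 of them. Scaled H3K9ac counts did not rise with H3K4me3. In well-watered and stressed plants they went from 42.6 and 33.1 to 41.2 and 31.0 at zma-MIR396a. At zma-MIR172c they went from 88.3 and 63.5 to 65.2 and 63.2. They fell in both waterings at zma-MIR159e and in well-watered plants only at zma-MIR156k. No microRNA gene was called for drought in any mark (edgeR 0 and DESeq2 0, edgeR unadjusted p under 0.05 at 10 genes for H3K4me3 and 4 for H3K9ac). For H3K27me3 only 1 microRNA gene was tested.

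By the rule of size, zma-MIR396a was higher at T7 for H3K4me3 in well-watered (0.80, 0.48 to 1.13) and in stressed plants (0.93, 0.49 to 1.41). Other microRNA genes met the rule in 1 watering: zma-MIR162 (0.73), zma-MIR166j (1.44) and zma-MIR172d (1.07) were higher and zma-MIR159e (-0.73) lower in well-watered plants, and zma-MIR166d (1.12) was higher and zma-MIR156k (-0.84) lower in stressed plants. Of these, zma-MIR172d (0.97) no longer met the rule with the trend on enrichment removed. Relative to background genes the ratios of zma-MIR396a and zma-MIR162 in well-watered plants were -0.027 and -0.10. Over the 116 tested genes the median H3K4me3 ratio of T7 over T0 was 0.21 in stressed plants, above all 10000 random lists matched on counts, and 0.26 in well-watered plants, at percentile 72.2. The median of the list between the stressed and the well-watered T0 libraries was 0.20 (percentile 9.7), and -0.18 (percentile 0.05) with the trend on enrichment removed. This comparison shares the stressed T0 library with that over time in stressed plants. After the same removal the median over time was 0.23 in stressed plants, again above all random lists, and -0.05 in well-watered plants (percentile 30.0). For H3K9ac over 137 genes it was 0.11 (percentile 5.45) in well-watered and -0.05 (percentile 24.7) in stressed plants, and -0.13 (percentile 0.8) and -0.05 (percentile 19.2) after the removal.

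**Figure D3:**
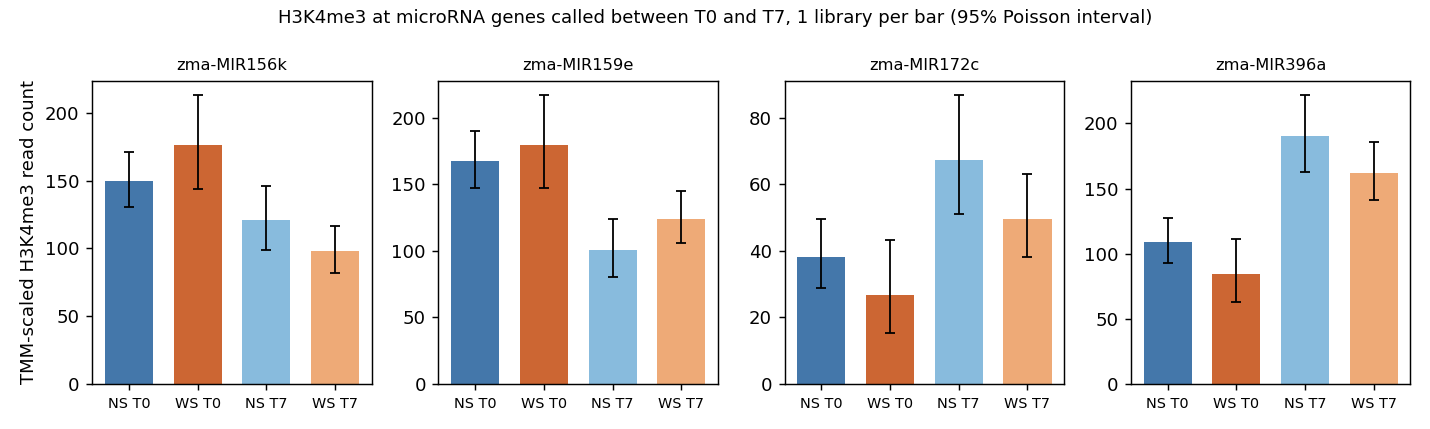
TMM-scaled H3K4me3 read counts (y axis) in the 4 libraries (x axis: NS well watered, WS stressed, T0 end of stress, T7 after recovery) at the microRNA genes called between T0 and T7, with bars of 1 library each and 95% Poisson intervals of the count. At zma-MIR396a counts stand at 109 and 84.7 at T0 and at 190 and 162 at T7, and at zma-MIR156k at 150 and 176 at T0 and at 121 and 98.2 at T7, well watered before stressed.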

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

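All tests reported in this part were chosen after the result was seen, except thinning the libraries to equal totals. Drought effects differed between T0 and T7 at single genes. For H3K4me3, 5 genes met the rule in opposite directions, each higher in stressed plants at T0 and lower at T7, and the difference was not tested at these genes as a group. Among them were Zm00001d028574 (0.65 at T0 and -0.64 at T7), where H3K9ac was also higher at T0 (1.37), and Zm00001d046079 (1.32 and -0.79). With the trend on enrichment removed 2 genes met it so, and these were not among them, since the ratio at T7 was then -0.58 for the former, short of 1.5-fold, and the interval of the ratio at T0, 0.60, held 1 for the latter. For H3K9ac, 2 genes met the rule in the same opposite directions, Zm00001d046256 (1.02 and -0.94) and Zm00001d028300 (0.61 and -0.64), and this difference was not tested. With the trend removed 0 did, as their ratios at T0 were then 0.40 and 0.18. A test of the difference between the drought effects over all H3K4me3 genes called 100 genes, 99 of them with a lower drought effect at T7 than at T0, with median log2 ratios of 1.14 at T0 and -0.32 at T7 (edgeR quasi-likelihood test; DESeq2 0, with unadjusted p under 0.05 at 100). Of the 100 genes 31 were H3K4me3-marked, and with the trend on enrichment removed 67 were called, 54 of them among the 100. Other settings called 97 (DESeq2 size factors), 126 (total counts), 155 (trend on abundance removed), 54 (no filter) and 104 (trend on whole-gene enrichment removed, 94 of them among the 100). The same test called 0 genes for H3K9ac (unadjusted p under 0.05 at 2720; DESeq2 0, with 16) and 0 for H3K27me3 (2212; DESeq2 0, with 29). For H3K9ac 3 genes each were called with total counts and with the trend on abundance or on enrichment removed, and for H3K27me3 2 with DESeq2 size factors and 4 each with the trend on abundance removed and with no filter.

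At T0 both active marks were lower at strongly marked and higher at weakly marked genes in stressed than in well-watered plants, a difference between the top and bottom quintiles of enrichment of -0.73 for H3K4me3 and -0.63 for H3K9ac. In the unstressed pair of T7 and T0 libraries H3K9ac had the same trend, at -0.63, so that it also arose without drought. Both pairs share the single well-watered T0 library, however. This pair therefore cannot tell how much of the trend between waterings at T0 came from drought. For H3K4me3, the greater depth of the well-watered T0 library is argued against by thinning all 4 libraries to equal totals, which left -0.69. The H3K9ac libraries were not thinned. A higher contrast of the well-watered T0 immunoprecipitations is a candidate explanation, since the H3K4me3 trend of the unstressed pair was -0.71, and a state of well-watered leaves at T0 that drought and a further week both altered stays open and untested. With enrichment over whole-gene counts the trends were smaller but again alike in both pairs, at -0.38 and -0.49 for H3K4me3 and -0.15 and -0.16 for H3K9ac. The only whole chromatin came from control plants at T0, so that a difference between groups in chromatin itself was not tested. The shared direction of H3K4me3 and H3K9ac at genes taken for H3K4me3 was still there with the trend removed, at 76.9% of 229 higher and 76.4% of 140 lower genes against 47.5% and 52.6% in random lists, while at genes lower for H3K9ac it depends on the window, at 48.4% of 31 against 50.1% in random lists with the 1 kb trend removed and 72.3% of 202 against 47.2% of all marked genes with the whole-gene trend removed.

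H3K27me3 at T7 was higher at H3K27me3-marked genes of previously stressed plants. A rise during recovery as the whole cause is argued against by a median of 0.11 for marked genes between the stressed T7 and T0 libraries. This lies below the 0.29 seen between waterings, but each value rests on a single pair of libraries and may carry a difference in their contrast. A lower contrast of the well-watered T7 library and a loss with age in well-watered plants cannot be told apart. Removal of the trend on enrichment, which left 28 genes higher against 144 before, ends any shift at marked genes whatever its cause, and the median of -0.27 for marked genes between the well-watered T7 and T0 libraries rests on the same single library.

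The change of H3K4me3 from T0 to T7 was weighed against technical causes. At genes called lower, noise of the H3K4me3 libraries alone is argued against by H3K9ac, which was lower in stressed plants at 71.0% of them. At genes called higher it is argued against in well-watered plants, where the H3K9ac median of the 180 marked ones was 0.02 against -0.17 in random lists, and with the trend on enrichment removed 0.06 against -0.01 over 427, both at percentile 100. In stressed plants it cannot be told apart, since the H3K9ac median lay at percentile 38.9. Library contrast that acts as a trend on enrichment is argued against as the whole cause at 171 of the 1392 genes. These were called again in the same direction after removal of the trend on 1 kb enrichment and, separately, of that on whole-gene enrichment. The 171 had also been picked for a large change, and library contrast in any other form was not tested at them. The others lost their call after at least one removal, with 855 of all called again for the 1 kb window and 180 for whole-gene counts. As a set, at least 80.2% of their median log2 change was left. They had been called for a large change, however. In the highest quintile of enrichment the median ratio over time was only -0.12 in well-watered and -0.07 in stressed plants. Most of the change at strongly marked genes was thus bound to be left, and for the set this is no test of library contrast. At those called lower the median log2 change was -0.52 before and -0.42 after either removal (median SE 0.13 before, 0.12 and 0.13 after). At those called higher it was 0.61 before and 0.50 and 0.62 after (0.16 before, 0.14 and 0.17 after). Much of the loss of calls with whole-gene counts lay in the prior degrees of freedom, which were 16.0 in place of 43.0, since with 43.0 in the same fit 686 were called again, 256 higher and 430 lower. With the trend on 1 kb enrichment removed they were 156.6, which eases calls. The 855 called again there thus owe part to the fit, and a count with 43.0 is not given. Noise larger than the fit assumes is argued against at genes called lower by the 113 genes lower at T7 in both waterings, where independent lists would give 10.8, while 19 went in opposite directions, where 11.3 would be given. With the trend removed these were 58 against 5.33 and 13 against 6.63. With that trend removed 14 genes were higher in both waterings against 1.74, beside the 13 in opposite directions. These 14 are few beside the 310 genes called higher, so that noise at that set is not settled. The 9 against 2.43 before removal were too few to decide. A change with the age of the plants may therefore be part of the pattern at genes called lower, but both active marks could come from the same chromatin, the sampling day is shared by all libraries of a time point, and neither was tested.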

How the results depend on the processing

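The trend on enrichment and its form over whole-gene counts were chosen after the data were examined, the other settings were planned. Leaving out a library leaves no residual degree of freedom and was not run, the fixed gene lists and list medians could not be computed, and other splits need 3 libraries a group. Depth limits H3K9ac and H3K27me3 most, where a minority of simulated 2-fold changes were found. Values below are those that moved, higher before lower, and unless said otherwise the cause was not tested. Of the results that answer a comparison, 23 kept their size and direction with DESeq2 size factors, 21 with total counts, 21 with no filter, 24 with the trend on abundance removed, 14 with the trend on enrichment removed, 20 with that on whole-gene enrichment of the active marks, 9 with a filter at 200 counts and 8 with background genes. Of values at single genes and of smaller counts, 74, 74, 7, 72, 73, 57, 2 and 50 did so, and 3 turned direction, all with background genes.

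Scaling on background genes moves all ratios of a comparison at once, by its construction. It gave 32 and 16777 genes for H3K4me3 drought at T0, 21 and 21148 for H3K4me3 time in well-watered plants, 12 and 5056 for H3K9ac drought at T0, 81 and 29 for H3K9ac drought at T7, and 14 and 4437 for H3K9ac time in well-watered plants. It reversed Zm00001d028574 at T0 (H3K4me3 -0.065) and zma-MIR396a (-0.027) and zma-MIR162 (-0.10) over time in well-watered plants. Scaling by total counts gave 169 lower genes for H3K4me3 and 210 for H3K9ac at T0 and 1 H3K9ac time call. DESeq2 size factors gave 2 H3K4me3 drought calls. DESeq2 called 0 genes for H3K4me3 drought, H3K4me3 time and H3K9ac drought, and its recovery on simulated counts was below that of edgeR. It still found 74% of simulated 4-fold H3K4me3 effects, which were set equal at both times. At Zm00001d054081 (-2.54) the effects differed between times, and the counts in stressed plants were 15 and 11. The simulation therefore cannot tell why DESeq2 did not call this gene.

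Removing the trend on abundance gave 168 lower genes for H3K4me3 and 135 for H3K9ac at T0, 144 lower for H3K9ac time in well-watered plants, 52 H3K4me3 drought calls and 6 H3K9ac time calls. Spearman correlations of T0 with T7 were then 0.0056 (H3K4me3) and -0.0024 (H3K9ac), and of H3K4me3 with H3K9ac 0.1109 at T0 and 0.0079 at T7. Removing the trend on enrichment gave 281 and 161 genes for H3K4me3 drought at T0, 371 lower for H3K4me3 time, 113 lower for H3K9ac drought at T0, 102 and 121 for H3K9ac time, 23 lower for H3K27me3 drought at T0, 28 higher at T7 and 52 lower for H3K27me3 time, each time in well-watered plants. It gave 2 calls each for H3K4me3 drought, H3K9ac drought, H3K9ac time and H3K27me3 time. Correlations of T0 with T7 were 0.0143, -0.0073 and -0.0174 for H3K4me3, H3K9ac and H3K27me3. Between marks they were 0.0987 (H3K4me3 with H3K9ac, T0), -0.0061 (H3K4me3 with H3K27me3, T7) and 0.0049 (H3K9ac with H3K27me3, T7). The trend on whole-gene enrichment gave 183 H3K4me3 time calls and correlations of 0.2342 (H3K4me3 with H3K9ac, T0), -0.0089 (H3K4me3 with H3K27me3, T7) and 0.0089 (H3K9ac with H3K27me3, T7).

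A filter at 200 counts tests fewer genes. It gave 122 lower genes for H3K4me3 and 41 for H3K9ac at T0, 375 lower for H3K4me3 time, 193 and 44 for H3K9ac time, 10 and 20 for H3K9ac drought at T7, 11 and 21 for H3K27me3 drought at T0, 18 lower at T7 and 15 higher for H3K27me3 time, again in well-watered plants. Correlations of T0 with T7 were 0.0587, -0.0128 and -0.1138 for the marks in the same order. Between marks they were 0.1684 (H3K4me3 with H3K9ac, T0), and at T7 0.0598, 0.0961 (H3K4me3 with H3K27me3) and -0.0492 (H3K9ac with H3K27me3). With no filter on low counts, 988 genes were lower for H3K4me3 time in well-watered plants, and calls were 13 for H3K4me3 drought and 1 for H3K27me3 time.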

Other observations

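Of the tests in this part, the MIR156 family median and the MIR396 median with the trend on enrichment removed were chosen before these values were seen, but after the calls at zma-MIR156k and zma-MIR396a were known. The MIR396 family was picked after its uncorrected median had been seen. The comparisons of other families and of H3K27me3 at H3K4me3-called genes were chosen after their results. MicroRNA families with at least 5 tested members gave 42 medians over 2 marks and 2 effects, and 7 lay outside the central 95% of random lists matched on counts. For H3K4me3 the MIR167 family, whose microRNA acts on auxin response factors, had a median log2 change over time of 0.47 (6 of 7 genes above 0, percentile 97.8; 98.3 with the trend on enrichment removed) and a median drought effect of -0.17 (3 of 7 above 0, percentile 1.55; 3.82 with the trend removed, inside the central 95%). With no filter on low counts this effect was 0.04 (5 of 9 above 0), so that no direction is read from it. The MIR166 family, whose microRNA acts on class III HD-ZIP transcription factors, had a median drought effect of -0.13 (3 of 8 above 0, percentile 1.77; 1.65 with the trend removed), and the MIR156 family one of 0.22 (8 of 10 above 0, percentile 98.4; 97.26 with the trend removed, inside the central 95%; 0.11 with no filter). For H3K9ac the MIR164 family, whose microRNA acts on NAC transcription factors, had a median change over time of -0.32 (2 of 7 above 0, percentile 1.46; 0.75 with the trend removed).

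Genes called lower for H3K4me3 at T7 had a median H3K27me3 ratio of T7 over T0 of 0.07 in stressed plants (percentile 99.8 of random lists matched on counts) and 0.02 in well-watered plants (percentile 76.2), over 881 genes carrying H3K4me3. With the trend on enrichment removed the medians were 0.04 (percentile 81.7) and 0.06 (percentile 99.5) over 487 genes. At Zm00001d013259 in well-watered plants H3K27me3 was lower at T7, with 455 against 936 counts (-0.84, -1.01 to -0.68), and H3K4me3 higher (1.05, 0.61 to 1.49). With the trend on enrichment removed its H3K27me3 ratio was -0.54 and no longer met the rule.

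The hypothesis that H3K4me3 fell from T0 to T7 over the MIR156 family as plants left the juvenile phase was not borne out. The single call at zma-MIR156k stood beside a family median of -0.06 over 10 tested genes, at percentile 37.6 of random lists. A further hypothesis, that H3K4me3 rose over the MIR396 family, was drawn from the uncorrected values, with 7 of 7 tested genes above 0, a median of 0.48 and percentile 99.92, so that these values are no test of it. Judged by random lists, it did not hold once the trend on enrichment was removed, with a median of 0.18 at percentile 93.3. All 7 of 7 genes were still above 0, so that a smaller rise is not excluded. Library contrast may account for part of the rise. The drought effect at the same family was -0.28 (1 of 7 genes above 0, percentile 0.11; 1.04 with the trend removed), which was not a hypothesis beforehand.

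The counts of Zm00001d000557 and Zm00001d040945 were nearly identical at T7, 65 and 79 in the H3K4me3 libraries of stressed and well-watered plants for each, so their lower H3K4me3 (-0.86 and -0.86) and H3K9ac (-1.15 and -1.13) ratios count as 1 observation.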
